A study of Mus musculus with 8 samples.

How the data were processed

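The series holds 8 single-cell libraries of peritoneal cells from tumour-bearing mice, 1 library per group, each pooled from 4 mice. Groups were taken from the treatment, time and response labels. The deposited files hold raw UMI counts per gene and barcode in sparse matrices, made with Cell Ranger 6.0.0, or 6.0.2 for both day 28 libraries, per the file headers, on a gene list of 32289 features that includes the added sequences hFRa, GFP, BiTE and Luciferase. The mm10 build and Seurat version 5 are named per the submitters' processing notes, and how Seurat was used is not given in the sources used here. The deposited matrices held 61390 barcodes, each with at least 500 UMIs, so a filter on UMIs appears to have been applied before deposit, and whether doublets had been removed is not given in the sources used here. Gene positions were taken from an annotation of GRCm38 by gene identifier.

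Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Doublet scores were computed per library with the Scrublet method in scanpy 1.11.5, and the highest-scoring 0.8% of cells per 1000 cells in the library were removed, 3511 in all, which left 54114 cells. Per library this removed 209, 606, 256 and 167 cells at day 7 and 591 (durable), 476 (progressive), 478 (day 28) and 728 (vaccine) cells. Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1.0 gave 33 clusters over the 8 libraries together. No batch integration was used because library and group are the same thing. The added sequences were kept out of clustering. scikit-learn 1.9.0, scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.

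Clusters were named from marker lists fixed before the data were examined, as were the gene lists, the rule for named genes, the filters on cells and most alternatives. The scoring was set afterwards. A cluster took a name when the mean log2 ratio of that type's markers to the mean of all clusters was at least 0.8 with a margin of 0.5 over other classes, at least 3 markers were detected in 10% of its cells, its top 10 genes held no more markers of another class than its own, and it did not combine a median UMI count under 0.333 of the library median with no own marker among those genes. Clusters with 3 or more haemoglobin genes or Alas2 among their top 10 formed a haemoglobin-led group. Monocyte markers define a class of their own under the fixed design. An earlier pass had joined them to macrophages, contrary to that design, and was replaced. The join is kept as an alternative, under which macrophage-like cells of the progressive library are 26.3% of cells in place of 0.953%, 10.8% in place of 9.39% with control T cells and isotype, and 35.2% in place of 29.6% with control T cells and anti-PD-1.

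Raw counts were summed per library and class and expressed as CPM of the class sum. A log2 ratio has a prior of 0.5 counts. Class sums have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios of 2 sums conditional exact intervals, all at 95% and for counting error only, since mice were pooled and no spread between animals was measured. A count of 0 was given a floor of 3 counts. The 16 gene lists covered cytotoxic effector, inhibitory receptor, naive and memory, and regulatory T cell genes, genes induced by interferon-gamma and by type I interferon, MHC class I and class II, inflammatory cytokines, alternative activation, large peritoneal macrophages, cell cycle, hypoxia and glycolysis, stress and dissociation, epithelial-mesenchymal and matrix genes, and germinal centre and B cell activation. Members with under 10 counts over both libraries were left out. A list's median log2 ratio was given a 95% interval from 300 Poisson redraws and a percentile among 10000 random lists of the same size matched on expression in 20 bins. A direction was stated only where the interval left out 0 and the percentile lay outside the central 95% of random lists, a rule set before the medians were computed. Classes with under 50 cells in a library were not compared.

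Named genes came from macrophage, T cell and epithelial classes with at least 100 cells in each library, or else the largest other class, which was B cell for the day 7 and outcome comparisons. A gene needed at least 20 counts in 1 library, and in the library where it was higher a CPM of at least 0.25 times its highest in any other class there. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and unnamed genes were left out. Genes were ranked by the interval bound nearest to no change, and up to 4 of the highest and 4 of the lowest per class are named. For the FR-B and anti-PD-1 effects a gene had to lie on the same side in both pairs. Members named beside a list are among its 2 highest and 2 lowest, or are named by the rule.

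The ratio step was tested on simulated counts. For durable against progressive epithelial-like cells (13797 genes), set log2 ratios of 1, -1, 2 and -2 came back at medians of 0.89, -1.09, 1.90 and -2.09, with 50 genes each. Intervals lay off 0 on the true side for 86.0%, 84.0%, 100% and 86.0% of these genes, and 96.0% of intervals held the true value. For FR-B against control T cell-like cells with isotype (10049 genes) they came back at 1.06, -0.98, 1.99 and -1.97, with 86.0%, 62.0%, 98.0% and 80.0% of intervals off 0 on the true side and 96.4% holding the true value. Lists of 15 genes raised by log2 1 were given a direction in 100 of 100 draws in both, and unchanged lists in 3 of 100 and 1 of 100. The counts were independent Poisson draws from the pooled profile of both libraries, and the raised lists came from the same 50 genes. These rates therefore leave out shifts between libraries, differences in cluster mix and shared regulation within a list.

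Alternatives were stricter filters on cells, no removal of doublets, Leiden resolutions 0.5 and 2.0, naming each cell by its highest marker score, median of ratios scaling, the mean of per-cell CPM, thinning to 1000 UMIs, subtracting 10% of the library profile, and a minimum of 50 counts for list members. Alternatives chosen after seeing the data were the join of monocyte with macrophage markers, naming haemoglobin-led clusters by their other markers, restricting to large peritoneal macrophage-like clusters, leaving out T cell subclusters led by NK, macrophage or B cell genes, and shares outside the epithelial class. No difference between day 7 and later libraries is taken as an effect of treatment, because sorting and time cannot be told apart from it.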

Results

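Single-cell RNA sequencing with a 10x Genomics 5′ kit, which counts unique molecular identifiers (UMIs) per gene and cell, was done on cells from the mouse peritoneal cavity. The mice had been given IE9-mp1-hFRa cells into the peritoneum, an ovarian tumour line that carries human folate receptor alpha (hFRa). They were then given T cells on day 5. FR-B T cells secrete a bispecific T cell engager (BiTE) against that receptor, and control T cells were given as the comparison. Anti-PD-1, which blocks an inhibitory receptor of T cells, was injected at 200 µg per dose, and an isotype antibody served as its control. The 4 libraries of day 7 after transfer combine both T cell products with both antibodies. The other 4 libraries all come from mice given FR-B T cells and anti-PD-1. At day 33 after transfer, 1 library held mice with a durable response and 1 held mice with progressive disease, defined by ascites and an abdominal circumference of at least 8.0 cm. At day 28 after transfer, 1 library held mice that had also received an adenoviral ovalbumin vaccine 2 weeks after transfer, and 1 held mice that had not.

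Each of the 8 groups was 1 library pooled from 4 mice, so no difference between groups was tested and every interval in the text covers counting error only. The libraries held 61390 barcodes, of which 54114 were kept as cells. Total UMIs per library at day 7 were 54569809 with control T cells and isotype, 26265562 with control T cells and anti-PD-1, 19136587 with FR-B T cells and isotype, and 16137926 with FR-B T cells and anti-PD-1. The later libraries held 58553518 (durable), 63318920 (progressive), 85362663 (day 28) and 74740487 (day 28 with vaccine). The median kept cell had 5484.5, 1810, 1624.5 and 2665 UMIs in the day 7 libraries in that order, and 4758, 5275.5, 4825 and 4678 UMIs in the later ones. Day 7 cells were sorted as live cells before loading, while the later cells were treated to lyse red cells, so the comparisons of groups set the later libraries only against each other. The depth gap between day 7 libraries can affect which cells passed the minimum of 500 UMIs, and so the shares of classes with little RNA.

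The target receptor was examined first. In the epithelial-like cells, hFRa stood at 1967 CPM (counts scaled to a fixed total per class; 95% Poisson interval 1952 to 1983) with control T cells and isotype, at 484 CPM (460 to 509) with control T cells and anti-PD-1, and at 321 CPM (308 to 334) with FR-B T cells and isotype. An hFRa UMI was present in 97.9%, 82.4% and 70.7% of these cells, and in 77.9%, 34.7% and 19.2% after each cell was thinned to 1000 UMIs, which left out 1, 0 and 7 cells. B cell-like cells of the control and isotype library, which should lack the receptor, had an hFRa UMI in 0.563% of cells (0.071% after thinning with 16 left out) at a median of 4019 UMIs, against 22445 UMIs in its epithelial-like cells. GFP, a further added sequence in the files' gene list, stood at 614, 967 and 1167 CPM in the same 3 libraries. Cluster 3 held 83.9% of the class with control T cells and isotype and 67.5% with FR-B T cells and isotype, and cluster 26 held 66.5% with control T cells and anti-PD-1. Within cluster 3 hFRa stood at 2161, 301 and 390 CPM in the 3 libraries, within cluster 12 at 1291, 199 and 193 CPM, and within cluster 26 at 1404, 617 and 124 CPM. The FR-B and anti-PD-1 library held only 2 epithelial-like cells, with 0 counts of hFRa or GFP. These added sequences lie outside the rule for named genes and were chosen after their values were seen.

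**Figure D1:**
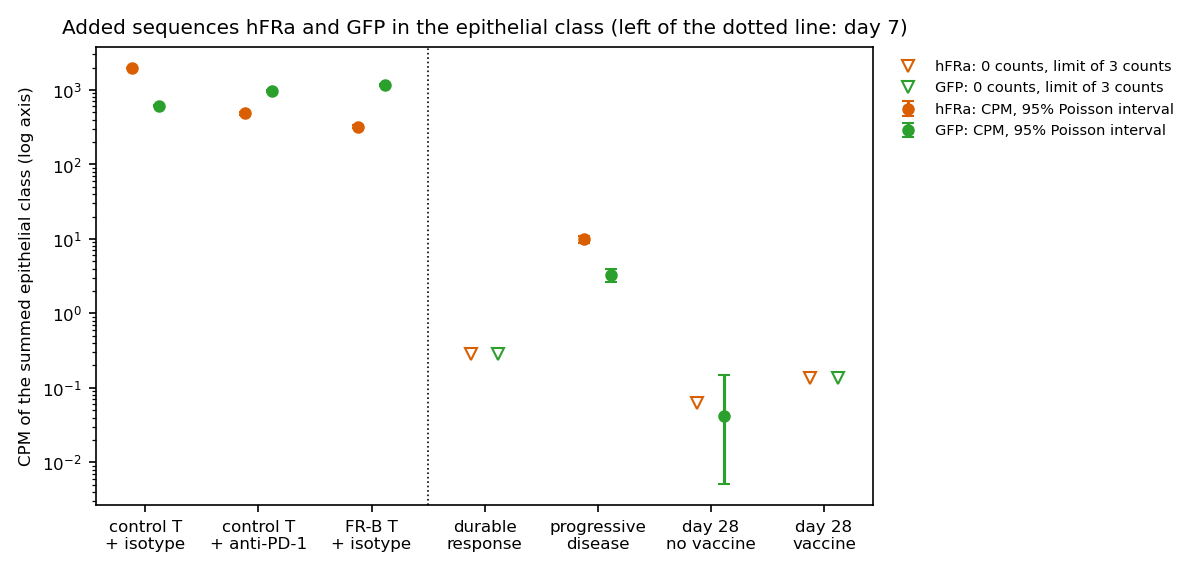
CPM of hFRa and GFP in the summed epithelial class of 7 libraries (log axis), with 95% Poisson intervals, and open triangles at 3 counts where the count is 0. hFRa is at 1967 CPM with control T cells and isotype and at 484 and 321 CPM in the next 2 libraries, while GFP is at 614, 967 and 1167 CPM.

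The kept cells fell into 33 clusters. Clusters were joined into classes named after markers, and the names mean "like" that cell type. Clusters that met no class stayed unnamed and held 5.79%, 9.98%, 12.3% and 14.3% of cells in the day 7 libraries in the order above, and 8.52% (durable), 27.2% (progressive), 14.6% (day 28) and 6.22% (vaccine) of the later ones. The T cell-like class also held subclusters led by genes of other cell types. A subcluster led by the NK genes Klra7, Klrb1c and Klre1 made up 18.45%, 8.14%, 10.98% and 16.6% of the class in the day 7 libraries in the order above, and 8.02%, 2.43%, 7.16% and 5.91% in the durable, progressive, day 28 and vaccine ones. Those led by macrophage genes (Lyz2, C1qa) and B cell genes (Cd79a, Ms4a1) made up at most 7.84% and 1.697%. Haemoglobin-led clusters held 13.3% of the progressive library and 0.676% or less of each other library.

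**Figure D2:**
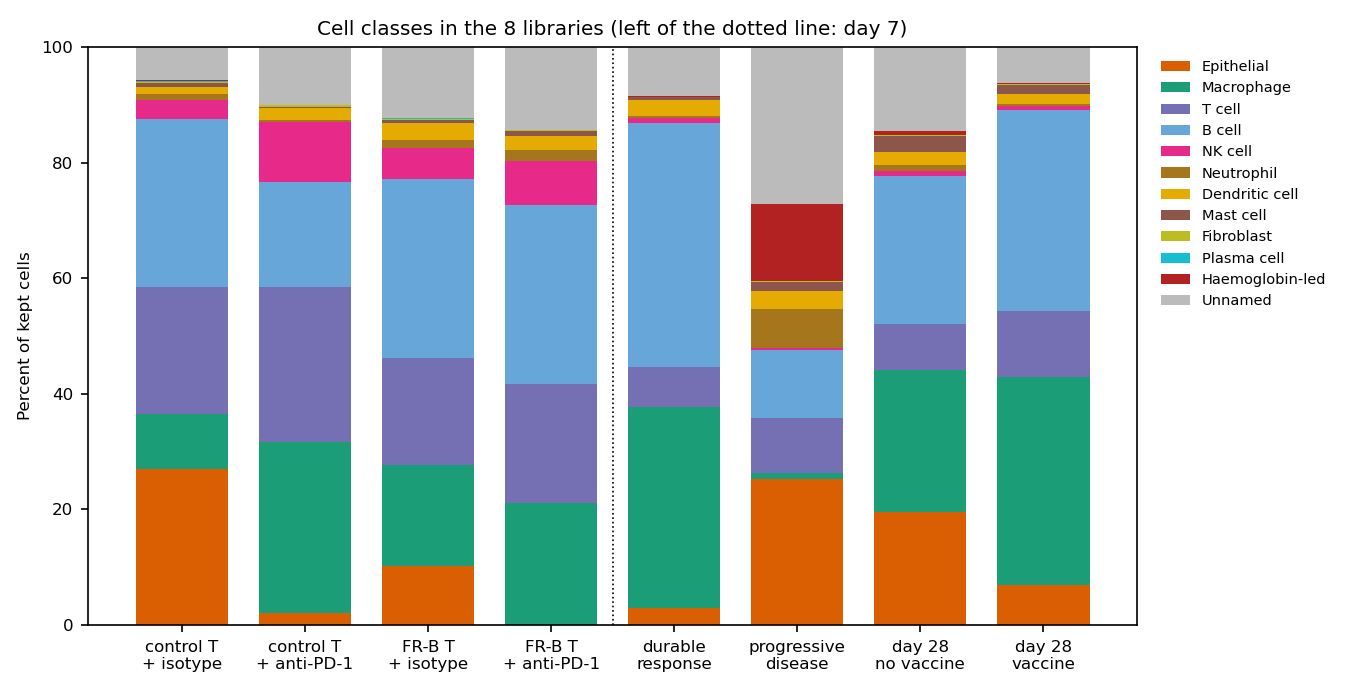
Stacked bars of the percent of kept cells in each class for the 8 libraries, day 7 to the left of the dotted line. Epithelial-like cells make up 27.0% of the control and isotype library and 0.045% of the FR-B and anti-PD-1 library.

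FR-B T cells were first compared with control T cells under isotype antibody, which asks what the engager product does without PD-1 blockade. Epithelial-like cells were 10.2% of the FR-B library (95% exact interval 9.40 to 11.03) and 27.0% of the control library (25.8 to 28.3), a difference of -16.8 percentage points (-18.3 to -15.4). Macrophage-like cells were 17.5% against 9.39%, NK cell-like cells 5.39% against 3.32%, T cell-like cells 18.6% against 22.1% and B cell-like cells 31.0% against 29.0%. In macrophage-like cells, the interferon-gamma-induced, type I interferon, MHC class II and cell cycle lists were higher in the FR-B library, and the large peritoneal macrophage and alternative activation lists were lower. In epithelial-like cells, the type I interferon and MHC class I lists were higher. Clusters of different character held most macrophage-like cells of the 2 libraries, cluster 2 (Cxcl13, Timd4, Vsig4) with 60.1% in the control library and cluster 6 (Retnla, Tnfaip2, Ccl9) with 65.7% in the FR-B library.

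The large peritoneal macrophage list in macrophage-like cells had a median log2 ratio of -1.06 (interval -1.16 to -0.94), with 10 of 11 members lower, at percentile 0 of 10000 random lists matched on expression. Its lowest members were Alox15 (-1.46), a lipoxygenase, and Garnl3 (-1.42). MHC class II genes, which present peptides to CD4 T cells, had a median of 1.02 (0.86 to 1.11), with 7 of 8 members higher, led by H2-Eb1 (1.25) and H2-Aa (1.18), while H2-DMb2 was at -0.49. The interferon-gamma list had a median of 0.74 (0.57 to 0.97; percentile 99.96) with 13 of 14 measured members higher, led by Gbp4 (2.00) and Iigp1 (1.82), 2 GTPases of cell-autonomous defence, while Cxcl9 was at -0.43. The type I interferon list stood at 0.86 (0.27 to 1.09) with 7 of 11 members higher, and the cell cycle list at 0.83 (0.67 to 1.10), the latter led by Rrm2 (2.76) and Mcm5 (2.17), which serve DNA synthesis. The alternative activation list stood at -0.45 (-0.60 to -0.19; 6 of 11 members lower), with Chil3 at -3.69 and Spp1 at -1.87 but Ccl8 at 2.61 and Folr2 at 2.28. In epithelial-like cells the type I interferon list stood at 0.55 (0.11 to 0.77) and MHC class I at 0.44 (0.40 to 0.51), the latter led by its regulator Nlrc5 (1.66) and H2-Q7 (1.35). Of the 35 pairs of list and class, 6 were higher, 2 were lower and 27 had no stated direction, among them the cytotoxic list in T cell-like cells (0.75, percentile 94.6). The median of all genes was itself shifted, by 0.50 in T cell-like, 0.34 in B cell-like, 0.21 in macrophage-like and 0.19 in epithelial-like cells, and the random lists carry that shift. With cells thinned to 1000 UMIs, the epithelial type I interferon median was -0.20, and the differences in the shares of macrophage-like cells changed sign under 5 of the other settings (down to -1.17 points), of B cell-like cells under 4 (down to -15.2 points) of NK cell-like cells under 1 (-0.22 points), and T cell-like cells reached -9.59 points. Other settings moved the large peritoneal list to as little as -0.27, MHC class II to 0.51, type I interferon to 0.46, alternative activation to between -0.77 and -0.13 and the cell cycle to between 0.53 and 1.56 in macrophage-like cells, and MHC class I to 0.25 in epithelial-like cells.

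With anti-PD-1, FR-B T cells were compared with control T cells to ask what the product adds to PD-1 blockade. Epithelial-like cells were 0.045% of the FR-B library (2 of 4406 cells, 0.005 to 0.164) and 2.10% of the control library (1.799 to 2.44). B cell-like cells were 30.8% against 18.2%, macrophage-like cells 21.1% against 29.6%, T cell-like cells 20.6% against 26.7% and NK cell-like cells 7.74% against 10.4%. The cytotoxic list had a higher median in the T cell-like and NK cell-like cells of the FR-B library. In T cell-like cells the inhibitory receptor and regulatory lists had lower medians, with members on both sides in the cytotoxic and inhibitory receptor lists. Interferon-gamma-induced genes were lower in macrophage-like, T cell-like and B cell-like cells, and type I interferon genes were higher in macrophage-like and B cell-like cells.

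The cytotoxic list had a median log2 ratio of 0.46 (0.32 to 0.62) in T cell-like cells with 8 of 14 members higher, and 0.57 (0.34 to 0.66) in NK cell-like cells with 12 of 14 higher. Gzma, a granzyme, was at 3.56 and Klrg1 at 1.90 in T cell-like cells, but the chemokines Ccl3 and Ccl4 were at -2.73 and -1.58. The inhibitory receptor list stood at -0.88 (-1.26 to -0.43; 7 of 11 members lower), with the checkpoint gene Lag3 at -1.90 and the costimulatory gene Tnfrsf9 at -2.36. The regulatory list stood at -0.50 (-0.80 to -0.31), with Ctla4 at -1.68 and Tnfrsf4 at -1.58, and the naive and memory list at -0.20 (-0.27 to -0.11), with 10 of 10 members lower. The interferon-gamma medians were -0.25 (-0.35 to -0.17) in macrophage-like, -0.36 (-0.52 to -0.28) in T cell-like and -0.40 (-0.75 to -0.31) in B cell-like cells, in which 13 of 13 members were lower. The chemokines Cxcl10 (3 against 75 counts, -3.01, -5.53 to -1.62) and Cxcl9 (-2.39) were the lowest members in macrophage-like cells. The type I interferon list was at 0.98 (0.54 to 1.11) there, led by Oasl1 (1.35) and Irf7 (1.35), and at 0.75 (0.39 to 1.17) in B cell-like cells. In macrophage-like cells the cell cycle list stood at -1.004 (-1.21 to -0.76) with 19 of 20 members lower, the inflammatory cytokine list at -0.86 (-1.25 to -0.34; 7 of 10 lower) and the stress and dissociation list at 0.47 (0.20 to 0.68; 7 of 10 higher). MHC class II in B cell-like cells stood at 0.32 (0.27 to 0.36) and MHC class I at -0.14 (-0.19 to -0.07), the latter at 0.08 with cells thinned and -0.27 with median of ratios scaling. Cluster 8 (Ccl5, Ly6c2, Cxcr6) held 43.3% of T cell-like cells in the FR-B library, where cluster 4 (Cd8b1, Il7r, Lef1) held 50.9% in the control library. T cell subcluster 9, led by Ccl4, Ccl3 and Lag3, held 2.20% of these cells in the FR-B library and 10.3% in the control library. Subclusters 2 and 6, led in part by Scaf11 and Rps29, held 10.0% and 2.42% in the FR-B library and 25.4% and 21.0% in the control library. The list ratios in T cell-like cells cannot be told apart from this split. Of 28 pairs, 6 were higher, 9 lower and 13 had no stated direction, and the median of all genes was shifted by 0.19 in macrophage-like, 0.20 in NK cell-like and 0.13 in B cell-like cells. The interferon-gamma median in macrophage-like cells moved to between -0.43 and -0.65 under 7 of the other settings. In that class type I interferon moved to 0.48, the cell cycle to -0.31, inflammatory cytokines to -0.48 and stress to 0.20. Without the subclusters led by genes of other cell types the inhibitory receptor list was at -0.42 and naive and memory at -0.32. With cells thinned the regulatory list was at -0.05, naive and memory at -0.02, interferon-gamma in T cell-like cells at -0.12 and in B cell-like cells at -0.68. Over all other settings the cytotoxic list in T cell-like cells was between 0.21 and 0.92, that in NK cell-like cells down to 0.38, and type I interferon in B cell-like cells between 0.40 and 1.28. MHC class II in B cell-like cells was down to 0.18. Under other settings the differences in shares reached -0.99 points (T cell-like), -0.85 (NK cell-like), -4.02 (macrophage-like) and 21.4 (B cell-like).

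Genes that lay on the same side in both antibody arms were named by size in 3 classes. In macrophage-like cells Folr2 (ENSMUSG00000032725, GRCm38 chromosome 7, 101839988 to 101857194, minus strand), the folate receptor beta gene of resident macrophages, was 4.85-fold higher with isotype (log2 2.28, 1.98 to 2.60) and 3.76-fold higher with anti-PD-1 (log2 1.91, 1.71 to 2.12). The cholesterol transporter Abca1 was 3.52-fold and 3.10-fold higher, the clotting factor XIII subunit F13a1 3.36-fold and 5.88-fold higher, and lipoprotein lipase Lpl 2.78-fold and 4.23-fold higher. The fatty acid carrier Fabp4 was 3.34-fold and 2.69-fold lower, Garnl3 2.67-fold and 2.97-fold lower, and the protease inhibitor Serpinb2 3.34-fold and 2.38-fold lower. In T cell-like cells the effector marker Klrg1 (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882) was 4.57-fold and 3.72-fold higher. The inhibitory NK receptor gene Klrc1 was 4.36-fold and 3.04-fold higher, and the integrin genes Itga1 (3.17-fold and 2.56-fold) and Itgb1 (2.68-fold and 1.99-fold), which pair as a collagen receptor, were also higher. T cell subcluster 1, led by Ifitm1, Gzma, Itgax and Itga1, held most cells with a BiTE UMI. It made up 18.4% of T cell-like cells against 14.5% with isotype, and 36.5% against 18.8% with anti-PD-1. The ratios were not computed within it. Osteopontin (Spp1) was 3.67-fold lower on 5 counts and 16.3-fold lower on 4 counts, Treml2 2.06-fold and 1.90-fold lower, and the nucleolar genes Npm1 (1.497-fold and 1.44-fold) and Nop10 (1.35-fold and 1.38-fold) were lower by less. In B cell-like cells Pgap1 (3.29-fold and 2.15-fold), the complement receptor gene Cr2 (2.15-fold and 2.22-fold), the insulin signalling gene Irs2 (2.60-fold and 2.57-fold) and the carboxypeptidase gene Cpm (2.27-fold and 1.84-fold) were higher. The antibody joining chain Jchain was 4.23-fold and 1.58-fold lower, the cytokine Mif 2.39-fold and 1.38-fold lower, S100a5 2.09-fold and 2.46-fold lower, and the RNA-processing gene Lsm7 1.59-fold and 1.47-fold lower. With cells thinned, Cr2 and Cpm were at log2 0.33 and 0.19, Jchain at -0.58 and Treml2 at -0.23 with isotype, and Spp1 was at -3.83 with isotype and -5.62 with anti-PD-1. With isotype the B cell-like cells had a similar mix, with clusters 0 and 1 at 44.1% and 48.6% in the control library and 49.7% and 47.5% in the FR-B library.

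Over whole lists the 2 FR-B ratios shared a side in 13 of 28 pairs of list and class, 10 higher and 3 lower in both. With median of ratios scaling it was 16 of 28, 4 higher and 12 lower, and with cells thinned 10 of 28, 7 higher and 3 lower. A direction was stated in both arms and on the same side for 1 pair, type I interferon genes in macrophage-like cells. It was stated and opposed for 2 pairs, the interferon-gamma and the cell cycle lists in macrophage-like cells. Across genes, which are not independent replicates, the 2 FR-B ratios correlated at Pearson r = 0.229 in macrophage-like (8633 genes), -0.135 in T cell-like, -0.187 in B cell-like and -0.039 in NK cell-like cells.

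Anti-PD-1 was compared with isotype in mice given control T cells, to ask what PD-1 blockade does without an engager. Epithelial-like cells were 2.10% of the anti-PD-1 library and 27.0% of the isotype library, a difference of -24.9 percentage points (-26.2 to -23.7). Macrophage-like cells were 29.6% against 9.39%, NK cell-like cells 10.4% against 3.32%, T cell-like cells 26.7% against 22.1% and B cell-like cells 18.2% against 29.0%. Interferon-gamma-induced genes were higher in each of the 4 classes measured, by the most in epithelial-like cells. Cytotoxic, inhibitory receptor, regulatory and cell cycle genes were higher in T cell-like cells. Macrophage-like cells carried more MHC class I and class II RNA and less of the large peritoneal macrophage genes.

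The interferon-gamma list had a median log2 ratio of 3.58 (3.49 to 3.70) in epithelial-like cells, led by the chemokine Cxcl10 (5.37) and the PD-L1 gene Cd274 (5.27), 2.08 (1.85 to 2.33) in macrophage-like cells, 1.55 (1.37 to 1.72) in B cell-like cells and 1.02 (0.91 to 1.25) in T cell-like cells. All measured members were higher, 15 of 15 in each of the first 2 classes and in T cell-like cells, and 13 of 13 in B cell-like cells. Type I interferon genes stood at 2.51 (2.23 to 2.84) in epithelial-like and 1.04 (0.74 to 1.23) in macrophage-like cells, and MHC class I genes at 1.93 (1.88 to 2.06) in epithelial-like, 0.51 (0.45 to 0.55) in macrophage-like and 0.35 (0.32 to 0.42) in B cell-like cells. In T cell-like cells the inhibitory receptor list stood at 1.40 (1.08 to 1.65), with 11 of 11 members higher and Havcr2 (36 against 2 counts, 4.04, 2.38 to 7.44) and Lag3 (3.44) at its head. The regulatory list stood at 1.08 (0.85 to 1.32), the cytotoxic list at 1.07 (0.76 to 1.34), led by Cx3cr1 (38 against 3 counts, 3.63, 2.18 to 6.17) and Ccl4 (2.78), and the cell cycle list at 0.83 (0.62 to 1.30). In macrophage-like cells MHC class II stood at 1.16 (1.10 to 1.20), the cell cycle at 1.00 (0.77 to 1.27) with 20 of 20 members higher, the large peritoneal list at -1.11 (-1.14 to -0.97) with 11 of 11 lower, and stress genes at -0.56 (-0.74 to -0.25). The cell cycle list in B cell-like cells was at -0.65 (-1.19 to -0.20), but at 0.10 with cells thinned and at 0.04 with 10% of the library profile subtracted. Cluster 26, itself led by interferon-induced genes, held 66.5% of the 170 epithelial-like cells of the anti-PD-1 library, and cluster 3 held 83.9% of those with isotype. Cluster 6 held 61.4% of macrophage-like cells with anti-PD-1 and cluster 2 held 60.1% with isotype. T cell subcluster 9, led by Ccl4, Ccl3 and Lag3, held 10.3% of T cell-like cells with anti-PD-1 and 1.75% with isotype. The difference in T cell-like cells was -0.22 points with at least 1000 UMIs per cell and -3.00 points among cells outside the epithelial class, while under other settings macrophage-like cells were down to 4.43 points and B cell-like cells to -22.25. Other settings moved, in macrophage-like cells, the large peritoneal list to -0.46, MHC class II to 0.72, the cell cycle to 2.25 and stress to -0.25, and in T cell-like cells cytotoxic genes to 0.56 and the cell cycle to 1.44. With cells thinned the regulatory list was at 0.23, epithelial type I interferon at 1.601 and MHC class I in B cell-like cells at 0.18. Of 35 pairs, 15 were higher, 3 lower and 17 had no stated direction, and the median of all genes was shifted by 0.19 in T cell-like and 0.12 in B cell-like cells.

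With FR-B T cells, anti-PD-1 was compared with isotype to ask what blockade adds to the engager product. Epithelial-like cells were 0.045% of the anti-PD-1 library and 10.2% of the isotype library, a difference of -10.2 percentage points (-10.98 to -9.36). Macrophage-like cells were 21.1% against 17.5%, T cell-like cells 20.6% against 18.6%, NK cell-like cells 7.74% against 5.39% and B cell-like cells 30.8% against 31.0%. Cytotoxic genes were higher in both T cell-like and NK cell-like cells, and naive, memory and regulatory genes were lower. Type I and interferon-gamma-induced genes were higher in macrophage-like, T cell-like and B cell-like cells.

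The cytotoxic list had a median of 0.61 (0.50 to 1.07) in T cell-like cells, with 13 of 14 members higher and Gzma (2.66) and the chemokine Xcl1 (1.89) leading, and 0.82 (0.66 to 1.04) in NK cell-like cells. Inhibitory receptor genes stood at 0.51 (0.20 to 0.80; 8 of 11 higher), naive and memory genes at -0.60 (-0.69 to -0.54), with Ccr7, a lymph node homing receptor, at -1.23, and regulatory genes at -0.69 (-0.91 to -0.31), with Ikzf4 at -1.34 and Ctla4 at -1.06. In macrophage-like cells type I interferon genes stood at 1.22 (0.84 to 1.45), interferon-gamma genes at 0.92 (0.83 to 1.14) with 14 of 14 members higher, MHC class II at 0.34 (0.27 to 0.39) and MHC class I at 0.32 (0.26 to 0.38). The large peritoneal list was at -0.28 (-0.38 to -0.19; 8 of 11 lower) and the cell cycle list at -0.71 (-0.97 to -0.50) there. In B cell-like cells type I interferon genes stood at 0.91 (0.47 to 1.21), interferon-gamma genes at 0.22 (0.04 to 0.43) and germinal centre and activation genes at -0.40 (-0.51 to -0.13; 6 of 10 lower), the last at 0.09 with cells thinned. In T cell-like cells the 2 interferon lists stood at 0.33 (0.04 to 0.81) and 0.30 (0.03 to 0.41). Cluster 8 held 43.3% of T cell-like cells with anti-PD-1 and cluster 4 held 49.4% with isotype. T cell subclusters 2 and 6, led in part by Scaf11 and Rps29, held 10.0% and 2.42% with anti-PD-1 and 20.9% and 15.9% with isotype. The list ratios in T cell-like cells cannot be told apart from this split. Cluster 1 held 58.6% of B cell-like cells with anti-PD-1 and cluster 0 held 49.7% with isotype. Of 28 pairs, 11 were higher, 5 lower and 12 had no stated direction, and the median of all genes was shifted by -0.20 in T cell-like and -0.19 in NK cell-like cells. The difference in macrophage-like cells changed sign under 5 of the other settings (down to -1.71 points), that in T cell-like cells was -0.06 points among cells outside the epithelial class, and that in B cell-like cells lay between -3.65 and 14.4 points. Shares of T cell-like cells reached 7.68 points and of NK cell-like cells 4.88. At the least, the macrophage medians were 0.59 (interferon-gamma), 0.73 (type I interferon), 0.02 (MHC class II), 0.18 (MHC class I), -0.11 (large peritoneal) and -0.06 (cell cycle). In T cell-like cells thinning gave -0.12 for the regulatory and 0.24 for the inhibitory receptor list (0.78 without the subclusters led by genes of other cell types), the cytotoxic list reached 1.09, and the type I and interferon-gamma lists lay between 0.15 and 0.52 and between 0.17 and 0.499, with interferon-gamma in B cell-like cells between 0.04 and 0.33.

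Genes on the same side with both T cell products were also named by size in 3 classes. In macrophage-like cells the interferon-induced GTPase Iigp1 (ENSMUSG00000054072, GRCm38 chromosome 18, 60376027 to 60392634, plus strand) was 9.62-fold higher with control T cells (log2 3.27, 3.01 to 3.54) and 2.498-fold higher with FR-B T cells (log2 1.32, 1.14 to 1.51). Gbp4 was 17.7-fold and 2.96-fold higher, Gbp5 5.69-fold and 2.43-fold, and Plac8 7.29-fold and 2.30-fold. Fabp4 was 2.86-fold and 2.30-fold lower, Ltbp1, which holds latent TGF-beta, 2.25-fold and 2.29-fold, Garnl3 2.15-fold and 2.39-fold, and Retnla, a gene of alternative activation, 2.68-fold and 1.78-fold. In T cell-like cells the chemokine Ccl1 had 214 counts with anti-PD-1 and 0 with isotype after control T cells, at least 80.2-fold higher against a floor of 3 counts. With FR-B T cells it had 60 against 2 counts, a log2 ratio of 3.44 (1.84 to 6.83). The transcription factor Bhlhe40 (2.52-fold and 2.21-fold), S100a6 (2.52-fold and 1.59-fold) and the chemokine receptor Ccr2 (2.35-fold and 1.71-fold) were higher. Lower were Lef1 (1.49-fold and 1.45-fold) and Klf2 (1.40-fold and 1.54-fold), transcription factors of resting T cells, the glucocorticoid-induced Tsc22d3 (1.43-fold and 1.79-fold) and the mismatch repair gene Mlh3 (3.504-fold on 8 counts and 2.77-fold on 16 counts). In B cell-like cells the interferon regulatory factor Irf1 (2.17-fold and 1.54-fold) and the interferon-induced Ifi213 (3.56-fold and 1.64-fold) were higher. Cd24a (1.58-fold and 1.36-fold), Napsa (1.30-fold and 1.18-fold), the serine synthesis gene Phgdh (1.32-fold and 1.31-fold) and Apobec2 (2.79-fold and 2.44-fold) were lower, the last 2 at log2 0.24 and 0.15 with control T cells once cells were thinned. Thinning also gave Gbp5 1.72, Mlh3 -1.04 and Ifi213 0.58 with control T cells and Ccl1 4.57 with FR-B T cells. Over whole lists the 2 anti-PD-1 ratios shared a side in 22 of 28 pairs, 14 higher and 8 lower in both. It was 16 of 28, 13 higher and 3 lower, with the mean of per-cell CPM, and 19 of 28, 16 higher and 3 lower, with cells thinned. A direction was stated in both on the same side for 9 pairs and on opposite sides for 2, the regulatory list in T cell-like and the cell cycle list in macrophage-like cells. Across genes the 2 ratios correlated at Pearson r = 0.026 in macrophage-like, -0.310 in T cell-like, -0.490 in B cell-like and -0.292 in NK cell-like cells.

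**Figure D3:**
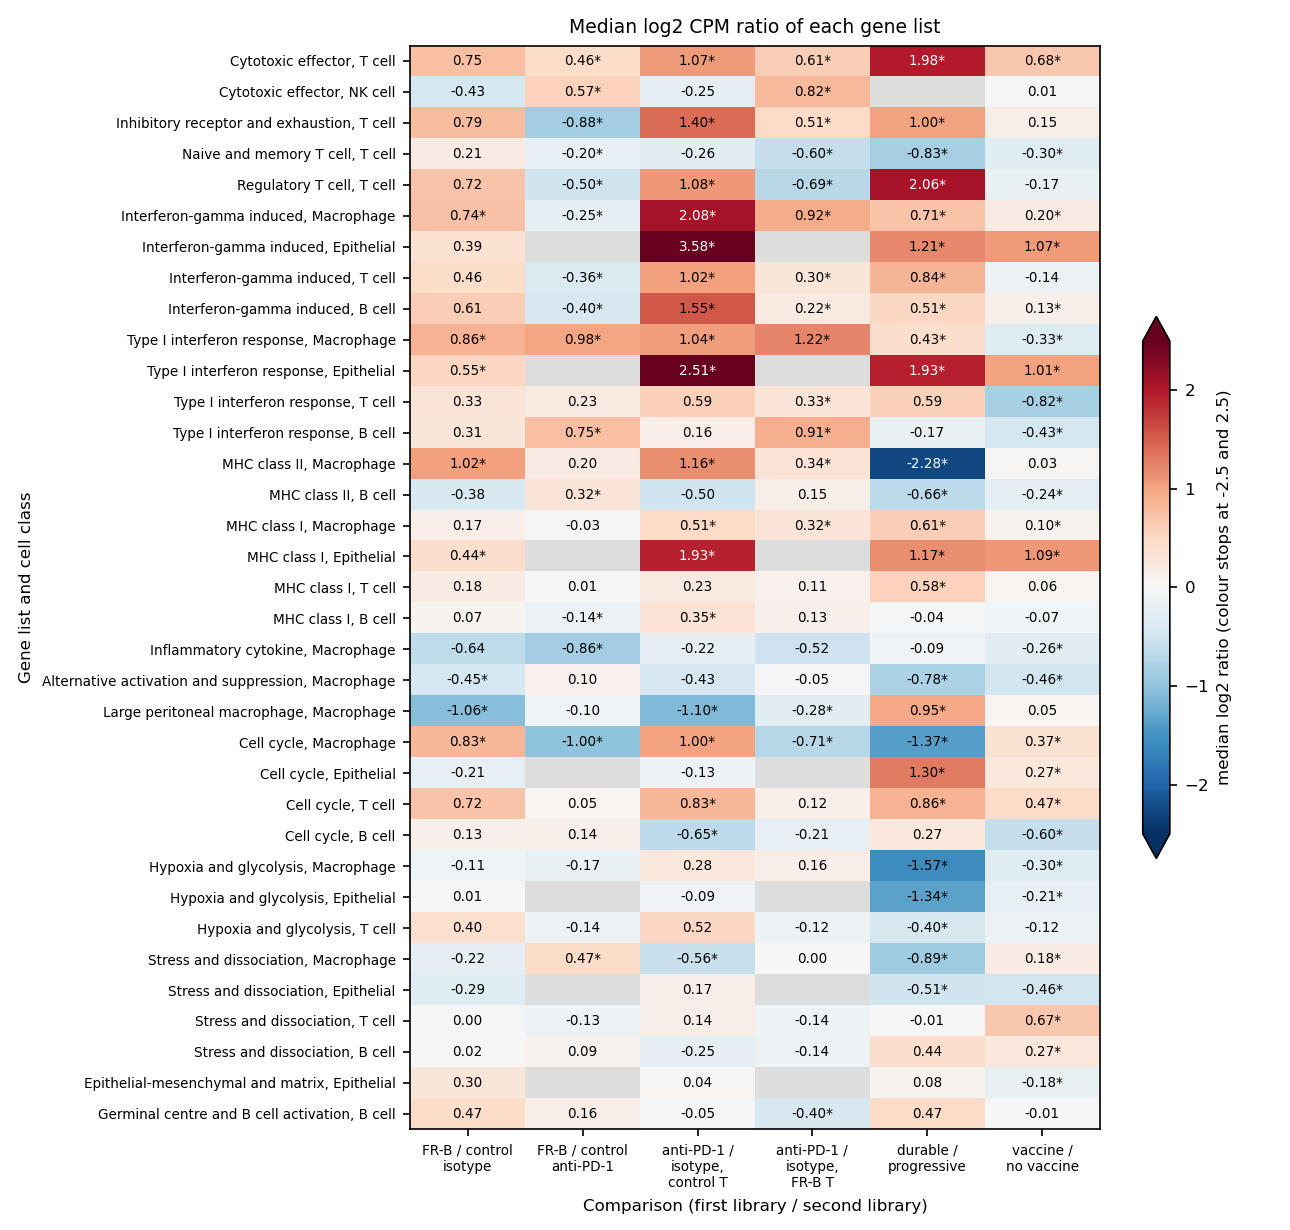
Heat map of the median log2 CPM ratio of each gene list and class (top to bottom) in the 6 comparisons (left to right), with a star where a direction was stated and grey where a class had too few cells. The interferon-gamma list in epithelial-like cells reaches 3.58 for anti-PD-1 with control T cells, and the MHC class II list in macrophage-like cells is at -2.28 for durable against progressive. The latter rests on 69 macrophage-like cells of the progressive library and is at 0.19 at Leiden resolution 2.0.

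Mice with a durable response were compared with mice with progressive disease at day 33, to ask how the peritoneal cells differ with outcome after the same treatment. Epithelial-like cells were 2.90% (2.54 to 3.29) of the durable library and 25.3% (24.3 to 26.3) of the progressive one. B cell-like cells were 42.2% against 11.6%, macrophage-like cells 34.8% against 0.953%, T cell-like cells 7.01% against 9.66% and neutrophil-like cells 0.362% against 6.81%. In T cell-like cells of the durable library, cytotoxic, inhibitory receptor and regulatory genes were higher and naive and memory genes lower. In epithelial-like cells, interferon, MHC class I and cell cycle genes were higher and hypoxia genes lower. An hFRa UMI was present in 0 of 232 durable and 21 of 1829 progressive cells of this class. The class is therefore not established as tumour cells. The macrophage-like class of the progressive library held only 69 cells, while cluster 7 (Hmox1, Trem2, Lyve1, Folr2, Arg1), which the naming rule left unnamed, held 24.1% of that library and 0.624% of the durable one. Its highest marker score was for macrophages (2.16), so 0.953% does not mean that macrophages were nearly absent. With monocyte markers joined, macrophage-like cells were 37.6% of the durable and 26.3% of the progressive library.

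The cytotoxic list in T cell-like cells had a median log2 ratio of 1.98 (1.29 to 2.70) with 12 of 13 members higher, led by Klrg1 (24 against 0 counts) and Ccl4 (4.01; 193 against 9 counts), while Gzma was at -1.04. The regulatory list stood at 2.06 (1.10 to 2.71) with 7 of 7 members higher, led by Il2ra (45 against 3 counts, 3.36, 1.93 to 5.90), inhibitory receptor genes at 1.005 (0.69 to 1.48), MHC class I at 0.58 (0.49 to 0.63), interferon-gamma genes at 0.84 (0.55 to 1.22) and the cell cycle at 0.87 (0.61 to 1.34). Hypoxia genes were at -0.40 (-0.55 to -0.04; 8 of 11 lower) there, but at 0.12 with cells thinned and at 0.54 with 10% of the library profile subtracted. The naive and memory list was at -0.83 (-1.04 to -0.66) with 10 of 10 members lower, among them Ccr7 (-2.27) and Lef1 (-1.32). In epithelial-like cells type I interferon genes stood at 1.93 (1.62 to 2.19), the cell cycle at 1.30 (1.22 to 1.36) with 20 of 20 members higher, where the cycling cluster 12 (Ube2c, Cenpf, Top2a) held 39.2% of durable and 16.8% of progressive cells of the class, interferon-gamma genes at 1.21 (1.14 to 1.504) and MHC class I at 1.17 (0.95 to 1.24). Hypoxia and glycolysis genes were at -1.35 (-1.41 to -1.20) with 14 of 14 members lower, among them Adm (2 against 328 counts, -5.43, -8.80 to -3.89) and Bnip3 (-3.48), and stress genes at -0.51 (-0.71 to -0.39; 6 of 9 lower). The epithelial-mesenchymal and matrix list, at 0.08 (0.01 to 0.20; percentile 32.0), had no stated direction. In B cell-like cells interferon-gamma genes stood at 0.51 (0.07 to 0.98; 7 of 12 higher) and MHC class II at -0.66 (-0.71 to -0.63). In macrophage-like cells, on 69 cells in the progressive library, MHC class II stood at -2.28 (-2.44 to -2.12), hypoxia genes at -1.57 (-1.72 to -0.92), the cell cycle at -1.37 (-1.62 to -1.14), stress genes at -0.89 (-1.09 to -0.30; 7 of 10 lower), alternative activation at -0.78 (-1.75 to -0.13), large peritoneal genes at 0.96 (0.75 to 1.08), interferon-gamma genes at 0.71 (0.43 to 1.20; 11 of 15 higher), MHC class I at 0.61 (0.42 to 0.72) and type I interferon genes at 0.43 (0.06 to 0.88; 9 of 13 higher). With members of 0 counts set at the floor of 3 counts, hypoxia was at -1.86, stress at -1.25 and type I interferon at 0.28. Several of these macrophage values turned under other settings, MHC class II to 0.19 and the cell cycle to 3.77 at Leiden resolution 2.0 and type I interferon to -0.46 with cells thinned, while the interferon-gamma list moved to 1.73 with cells thinned and to 0.39 with the mean of per-cell CPM. With monocyte markers joined, alternative activation was at -3.28, but at -0.20 with 10% of the library profile subtracted. The join put large peritoneal genes at 4.10, and other settings moved hypoxia to -1.02, stress to -0.24 and MHC class I to 0.39. In the other classes they moved the cytotoxic list to 1.26, the T cell cycle list to between 0.55 and 2.29, B cell interferon-gamma to between 0.22 and 0.77, B cell MHC class II to -0.41 and epithelial stress to between -0.77 and -0.15. Neutrophil-like cells differed by -1.52 points with at least 500 genes and 1000 UMIs and by up to -8.74, macrophage-like cells by 11.3 points with monocyte markers joined, and T cell-like cells by between -1.5 and -5.7 points.

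By size, in T cell-like cells S100a4 was 11.2-fold higher in the durable library (log2 3.48, 3.06 to 3.97), Itgb1 10.7-fold higher, and the interleukin-33 receptor Il1rl1 was at 65 against 2 counts (log2 4.37, 2.77 to 7.76). Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392, plus strand), an insulin-like growth factor binding protein, was 26.9-fold lower on 71 against 1520 counts. Trnp1 was at -6.00 (-9.38 to -4.43) on 2 against 126 counts, Nme4 at -3.95 (-7.36 to -2.27) on 2 counts, and the muscle gene Neb 11.8-fold lower on 5 counts. Igfbp4 and Trnp1 lead T cell subcluster 4, which held 1.07% of T cell-like cells in the durable and 84.0% in the progressive library. In epithelial-like cells the transglutaminase Tgm5 (29.7-fold), the interferon-induced genes Ifit3 (24.1-fold) and Ifit1 (19.5-fold) and the histone gene Hist1h2ab (17.2-fold) were higher. Ndufa4l2 (ENSMUSG00000040280, chromosome 10, 127514967 to 127517154), a mitochondrial gene induced in hypoxia, had 2 against 2160 counts (log2 -8.15, -11.5 to -6.62). The metalloreductase Steap4 was at -5.52 (-8.02 to -4.18) on 3 counts and the choline phosphodiesterase Enpp6 at -5.50 (-8.87 to -3.96) on 2 counts. In B cell-like cells S100a6 (17.1-fold) and the scaffold gene Ahnak (16.7-fold) were higher, Ahnak2 was at least 18.8-fold higher (977 against 0 counts) and Gas7 stood at 1181 against 1 count (log2 5.50, 3.61 to 11.4). The germinal centre factor Mef2b was 57.4-fold lower on 6 against 21 counts, Jchain 23.1-fold, the surrogate light chain gene Vpreb3 18.3-fold and the phosphatase Dusp2 12.8-fold. With cells thinned the log2 ratios were 2.98 for Tgm5, 3.72 for Ifit3, 3.46 for Hist1h2ab, -4.77 for Ndufa4l2, -2.80 for Steap4 and -2.31 for Enpp6 in epithelial-like cells. They were -3.34 for Nme4 in T cell-like cells (-4.58 without the subclusters led by genes of other cell types, not thinned), and 3.93 for Gas7, -3.24 for Jchain and -3.07 for Vpreb3 in B cell-like cells. Different clusters held most B cell-like cells, cluster 0 (Ms4a1, Mzb1) with 72.8% of the durable library and cluster 1 (Ighd, Vpreb3, Fcer2a) with 91.2% of the progressive one. Different clusters also held most T cell-like cells, cluster 9 (Cd4, Tnfrsf4) with 56.1% and cluster 4 with 92.7%. Of 34 pairs, 15 were higher, 10 lower and 9 had no stated direction, and the median of all genes was shifted by 0.27 in epithelial-like, 0.17 in T cell-like, -0.26 in B cell-like and -0.20 in macrophage-like cells.

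Vaccinated mice were compared with unvaccinated mice at day 28, to ask what the adenoviral vaccine adds to FR-B T cells and anti-PD-1. Epithelial-like cells were 6.88% (6.36 to 7.43) of the vaccinated library and 19.6% (18.7 to 20.5) of the other. Macrophage-like cells were 36.0% against 24.5%, B cell-like cells 34.8% against 25.6% and T cell-like cells 11.3% against 8.10%. Cytotoxic genes were higher and naive and memory genes lower in T cell-like cells of the vaccinated library. In epithelial-like cells, interferon-induced and MHC class I genes were higher. With 0 hFRa counts in 606 vaccinated and 0 in 1421 unvaccinated cells, this class is not established as tumour cells either. Type I interferon genes were lower in T cell-like, B cell-like and macrophage-like cells.

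The cytotoxic list in T cell-like cells had a median log2 ratio of 0.68 (0.59 to 0.99) with 13 of 14 members higher, led by Gzma (3.14) and Cx3cr1 (3.02), and the naive and memory list stood at -0.30 (-0.36 to -0.19) with 9 of 10 members lower. The type I interferon list was at -0.83 (-1.12 to -0.55) there, with Isg15 at -1.38 and Usp18 at -1.23, at -0.43 (-0.61 to -0.10) in B cell-like cells and at -0.33 (-0.47 to -0.23) in macrophage-like cells with 13 of 13 members lower. In epithelial-like cells it was at 1.007 (0.91 to 1.09) with 13 of 13 members higher, MHC class I at 1.09 (1.05 to 1.11) with 12 of 12 higher, and the interferon-gamma list at 1.07 (0.89 to 1.27). The cell cycle list stood at 0.27 (0.24 to 0.31), where cluster 12 held 38.6% against 27.8% of the class, matrix genes at -0.19 (-0.22 to -0.12; 8 of 12 lower), hypoxia genes at -0.21 (-0.27 to -0.11) and stress genes at -0.46 (-0.56 to -0.30; 6 of 9 lower) in the same class. In macrophage-like cells alternative activation genes stood at -0.46 (-0.69 to -0.29), with Vegfa (6 against 14 counts, -2.11) and Spp1 (-1.83) lowest, hypoxia genes at -0.30 (-0.35 to -0.24), inflammatory cytokines at -0.26 (-0.56 to -0.04), the cell cycle at 0.37 (0.25 to 0.43), interferon-gamma genes at 0.20 (0.08 to 0.27) with 11 of 16 higher (0.53 with monocyte markers joined, 0.09 with the mean of per-cell CPM), stress genes at 0.18 (0.10 to 0.29) and MHC class I at 0.10 (0.07 to 0.14). In B cell-like cells the cell cycle was at -0.61 (-0.78 to -0.32), MHC class II at -0.24 (-0.27 to -0.23), interferon-gamma genes at 0.13 (0.02 to 0.23; 9 of 14 higher) and stress genes at 0.27 (0.07 to 0.58), and in T cell-like cells stress genes were at 0.67 (0.44 to 0.93; 5 of 7 higher) and the cell cycle at 0.47 (0.21 to 0.84). The germinal centre list in B cell-like cells, at -0.01 (-0.40 to 0.14), and the regulatory list in T cell-like cells, at -0.17 (-0.57 to -0.02; percentile 12.4), had no stated direction. Other settings moved, in macrophage-like cells, type I interferon to -0.12, alternative activation to between -2.04 and -0.28, hypoxia to -0.66, inflammatory cytokines to -0.51, the cell cycle to between 0.08 and 0.57, stress to between 0.04 and 0.30 and MHC class I to between 0.02 and 0.26. They moved type I interferon to between -0.73 and -0.25, the cell cycle to -0.05, MHC class II to -0.14, interferon-gamma to between 0.03 and 0.23 and stress to between 0.17 and 0.44 in B cell-like cells. They moved stress to 0.36 and the cell cycle to between 0.11 and 0.99 in T cell-like cells, and stress to -0.17 and matrix genes to -0.06 in epithelial-like cells. Shares differed by as little as 5.86 points (macrophage-like), 5.55 (B cell-like) and 2.10 (T cell-like).

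By size, T cell-like cells of the vaccinated library had 15.4-fold more Penk RNA (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), which encodes proenkephalin (log2 3.94, 2.90 to 5.52). The fractalkine receptor Cx3cr1 was 8.12-fold higher on 82 against 5 counts, granzyme gene Gzmb 2.52-fold, and the heat shock gene Hspa1b at least 4.51-fold (25 against 0 counts). Igfbp4 was 3.59-fold lower, the regulatory T cell factor Foxp3 2.98-fold on 32 against 52 counts, Isg15 2.60-fold and the cytokine suppressor Socs3 2.43-fold. Subcluster 4, led by Igfbp4, held 0.20% of T cell-like cells in the vaccinated and 8.52% in the unvaccinated library. Subcluster 5, led by Gzmk, Ccl5, Cx3cr1 and Gzmb, held 33.6% in the vaccinated and 17.7% in the unvaccinated library. The ratios of Cx3cr1, Gzmb and the cytotoxic list go with this mix and were not computed within subclusters. In epithelial-like cells the interferon-induced GTPases Iigp1 (6.54-fold) and Igtp (3.77-fold), Tcp11x2 (5.02-fold) and the lipase Pnpla1 (3.97-fold) were higher. Enpp6 was 9.71-fold lower, Angptl7 4.97-fold lower, the epoxide hydrolase Ephx2 at least 8.51-fold lower (0 against 55 counts) and the keratin Krt17 at -3.68 (-9.59 to -1.69) on 1 against 41 counts. In macrophage-like cells the circadian repressors Nr1d1 (2.72-fold) and Nr1d2 (2.65-fold) were higher, and Alb (2.95, 1.30 to 6.35) and Amot (2.61, 0.92 to 6.02) each rested on 2 counts in the unvaccinated library. Cx3cr1 (4.50-fold), the integrin Itgb5 (4.18-fold) and the scavenger receptor Marco (2.27-fold) were lower. With cells thinned, log2 ratios were 2.38 for Penk, 3.11 for Tcp11x2, -3.05 for Angptl7, -1.09 for Krt17, -4.91 for Cx3cr1 in macrophage-like cells and 1.5 for each of Alb and Amot. Cluster 8 held 38.1% of T cell-like cells in the vaccinated library and cluster 4 held 45.3% in the other, and among B cell-like cells the median of all genes was shifted by -0.10. Of 35 pairs, 13 were higher, 12 lower and 10 had no stated direction.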

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

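The tests of depth, tumour identity, product and clusters in this part were chosen after the results were seen, and the test across cell classes before. In the day 7 design 4 effects, on 3 pairs of list and class, had a direction stated in both arms and pointed opposite ways. With or without a stated direction, the FR-B ratios shared a side in 13 of 28 pairs and the anti-PD-1 ratios in 22 of 28. None of the differences between arms was tested, since each arm is 1 pair of libraries. The FR-B effect on interferon-gamma-induced genes in macrophage-like cells was 0.74 with isotype and -0.25 with anti-PD-1, a difference of 0.99 on the log2 scale. The FR-B effect on the cell cycle list in the same class was 0.83 and -1.004, a difference of 1.84, but the latter was -0.31 with no doublets removed. The anti-PD-1 effect on that list, which is the same contrast seen from the other side, was 1.00 with control T cells and -0.71 with FR-B T cells, a difference of 1.71, but the latter was -0.06 at Leiden resolution 2.0. Cluster 15, led in part by Mki67 and Top2a, held 2.4% (11 cells, control and isotype) and 5.8% (139, control and anti-PD-1) of macrophage-like cells. With FR-B T cells it held 4.1% (39 cells, isotype) and 2.0% (19, anti-PD-1). The cell cycle ratios above went the same way as these shares, which were not tested as the cause. The anti-PD-1 effect on the regulatory list in T cell-like cells was 1.08 and -0.69, a difference of 1.77, but 0.23 and -0.12 with cells thinned.

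Across genes, the anti-PD-1 ratios with the 2 T cell products correlated negatively in T cell-like (-0.310) and B cell-like (-0.490) cells. The contrast lines up with depth, at median UMIs of 1810 (control and anti-PD-1) and 1624.5 (FR-B and isotype) against 5484.5 (control and isotype) and 2665 (FR-B and anti-PD-1), so depth, or a difference in preparation shared by every cell type, might give this. The contrast of the 2 anti-PD-1 ratios correlated across 6824 genes at 0.744 between T cell-like and B cell-like cells, at 0.401 between macrophage-like and B cell-like and at 0.357 between macrophage-like and T cell-like cells. A shared shift had been predicted to give values above 0.5 in every pair, which 2 of the 3 did not reach, and no pair fell under the 0.2 that was to argue against it, so it cannot be told apart from a response that cell types share, with 1 library per group.

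The target receptor hFRa was lower in epithelial-like cells of the other libraries than in the control and isotype library. Depth alone is argued against for the control and anti-PD-1 library, where 34.7% of cells (27.6 to 42.4) had an hFRa UMI after thinning against 77.9% (75.6 to 80.1). A change in cluster mix is argued against as the whole cause in the 2 other day 7 libraries with enough cells, where hFRa within clusters 3, 12 and 26 stood at a log2 ratio of -1.19 or lower to the control and isotype library, and FR-B T cells as the only cause are argued against by the control and anti-PD-1 library, which received none and stood at 484 CPM (460 to 509) against 1967. For the 4 later libraries the epithelial-like cells might be mesothelial cells, but the median log2 ratio of 6 mesothelial markers to the control and isotype library was -0.33 (durable), 0.37 (progressive), -0.06 (day 28) and -0.35 (vaccine), and since the tumour line may carry these markers this cannot be told apart from tumour cells that lack the receptor. At day 7 GFP did not fall with hFRa, at 614 (control and isotype), 967 (control and anti-PD-1) and 1167 CPM (FR-B and isotype). In the later epithelial-like cells GFP stood at 0 (durable), 3.25 (progressive), 0.042 (day 28) and 0 CPM (vaccine). Those cells thus had little or none of both sequences and did not lack the receptor alone. Whether the tumour line carries GFP is not given in the sources used here. Loss of receptor-bearing tumour cells under treatment stays open and untested.

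Interferon-gamma-induced genes in macrophage-like cells were higher with anti-PD-1 after control T cells, at a median of 2.08. A change in cluster mix is argued against as the whole cause, since the median within cluster 2 alone was 2.20 (1.97 to 2.38), and within cluster 6 it was 1.57. Cell depth is argued against by a median of 1.79 with cells thinned to 1000 UMIs. A response to PD-1 blockade and a difference in preparation between the 2 libraries both stay open, and separate libraries of single mice from each group would be needed to decide.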

How the results depend on the processing

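The monocyte join, the naming of haemoglobin-led clusters, the restriction to large peritoneal macrophage-like clusters, leaving out T cell subclusters led by genes of other cell types and the shares outside the epithelial class were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of the list medians other than the interferon-gamma list in macrophage-like cells, 1916 values under alternatives stayed within their interval, 499 moved and 12 reversed, and of the shares other than the epithelial one 237 stayed, 69 moved and 18 reversed. The 12 reversed medians all belong to lists with a stated direction, so sign changes of the other lists need not be among them. Shares whose main interval held 0 were not counted as reversed when their sign changed. B cell-like cells for anti-PD-1 with FR-B T cells are an example, at -0.15 points and up to 14.4. For the epithelial share 37 values stayed and 11 moved, for the interferon-gamma list in macrophage-like cells 63 stayed and 20 moved, and neither reversed. The 8 alternatives to the 2 counts of pairs on the same side in both arms stayed within 1.5 times. The make-up of these counts moved more. For FR-B it went from 10 higher and 3 lower to 4 higher and 12 lower with median of ratios scaling. For anti-PD-1 it went from 14 higher and 8 lower to 13 higher and 3 lower with the mean of per-cell CPM. The cause was not tested. Depth can limit which day 7 cells passed the minimum and which genes were measured, which was not tested as a cause, and the progressive library had 69 macrophage-like cells.

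The moved epithelial differences in percentage points were these. With at least 500 genes and 1000 UMIs they were -13.5 (FR-B, isotype), -2.77 (FR-B, anti-PD-1), -14.2 (anti-PD-1, FR-B), -29.3 (durable) and -15.4 (vaccine). Naming by cell gave -9.35 (anti-PD-1, FR-B) and -14.6 (vaccine), no doublet removal -23.5 (durable), Leiden 0.5 -23.6 (durable) and -16.0 (vaccine), and naming haemoglobin-led clusters -25.5 (durable).

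Moved interferon-gamma medians in macrophage-like cells were, for FR-B with isotype, 0.97 with the stricter minimum and 0.53 with median of ratios. For FR-B with anti-PD-1 they were -0.57 with the stricter minimum, -0.62 at most 5% mitochondrial, -0.62 with no doublets removed, -0.55 and -0.65 at Leiden 0.5 and 2.0, -0.60 in large peritoneal clusters and -0.43 with median of ratios. For anti-PD-1 with FR-B T cells, in the same order without the last, they were 0.72, 0.68, 0.68, 0.69, 0.59 and 0.69. Anti-PD-1 with control T cells gave 1.79 when thinned. Durable against progressive gave 1.73 when thinned and 0.39 with per-cell CPM, and vaccination 0.49 named by cell and 0.53 with the monocyte join.

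Reversed shares, in percentage points, were these. For FR-B with isotype, macrophage-like cells were at -0.17 (stricter minimum), -0.50 (5% mitochondrial), -1.08 (no doublets removed), -1.14 (Leiden 0.5) and -1.17 (Leiden 2.0), B cell-like cells at -8.97 (stricter minimum), -8.87 (5% mitochondrial), -15.2 (Leiden 2.0) and -5.20 (outside the epithelial class), and NK cell-like cells at -0.22 (stricter minimum). For anti-PD-1 with FR-B T cells, macrophage-like cells were at -1.71, -1.47, -1.32, -1.21 and -1.17 under those first 5 settings, and T cell-like cells at -0.06 outside the epithelial class. For anti-PD-1 with control T cells, T cell-like cells were at -0.22 (stricter minimum) and -3.00 (outside the epithelial class). Cluster 6 took the macrophage name with a marker score of 0.95, near the minimum of 0.8. It held 11.5% of the FR-B and isotype library, against 2.20% with control and isotype and 16.5% with FR-B and anti-PD-1. These gaps exceed the main macrophage-like differences of 8.06 and 3.67 points, whose signs therefore depend on that name. Whether its cells lost the name under the reversing settings was not tested.

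Reversed list medians with cells thinned were -0.20 (type I interferon, epithelial-like, FR-B with isotype), 0.079 (MHC class I, B cell-like, FR-B with anti-PD-1), 0.10 (cell cycle, B cell-like, anti-PD-1 with control T cells), 0.091 (germinal centre, anti-PD-1 with FR-B T cells), and for durable against progressive -0.46 (type I interferon, macrophage-like) and 0.12 (hypoxia, T cell-like, in place of -0.40). Subtracting 10% of the profile gave 0.038 for that B cell cycle list and 0.54 for that hypoxia list. In macrophage-like cells, durable against progressive, the cell cycle was at 3.77 and MHC class II at 0.19 at Leiden 2.0, and the cell cycle at 0.14 named by cell and 0.14 with the monocyte join.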

Other observations

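The values in this part lie outside the comparisons of the report, were chosen after the data were seen, and were not tested. T cell-like cells split into 15 subclusters, of which 3 (Klra7, Klrb1c), 11 (Lyz2, C1qb) and 14 (Cd79a, Igkc) were led by genes of NK cells, macrophages and B cells. Subcluster 5 was led by Gzmk, Cx3cr1, Gzmb and Pdcd1 and had Cd8a in 63.0% of its cells, as in effector CD8 T cells. Subcluster 9 was led by Ccl4, Ccl3, Lag3 and Ifng and had Cd4 in 51.4%. Subcluster 10, led by Foxp3 and Il2ra, had Foxp3 in 59.3%. Subcluster 12, led by Cd163l1 and Blk with the gamma-delta receptor gene Trdc in 19.7% of cells, made up between 0.787% and 2.89% of T cell-like cells in the 8 libraries. Subcluster 4, led by Igfbp4, Trnp1 and Ddit4 with Cd8b1 in 40.2% of cells, came to 84.0% of T cell-like cells in the progressive library and 8.52% or less elsewhere, so it is mostly 1 library and need not be a cell type. Subclusters 2 and 6 were led in part by Scaf11 and Rps29, and both were mostly cells of the 2 day 7 libraries with the lowest median UMIs.

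The BiTE sequence was counted in T cell-like cells of both libraries that should hold the product at day 7. With FR-B T cells and anti-PD-1, 46 of 908 cells carried it (5.07%, or 2.43% after thinning with 44 cells left out), at 29.3 CPM (23.2 to 36.6), and 43 of the 46 lay in subcluster 1. With FR-B T cells and isotype, 6 of 1002 cells carried it (0.599%, or 0.760% after thinning with 476 cells left out), at 5.02 CPM (1.84 to 10.9), and 5 lay in subcluster 1. Median depths in the T cell-like cells were 2558.5 and 1028.5 UMIs. B cell-like cells, which should lack it, had 0 of 1358 and 1 of 1671 cells with a BiTE UMI at medians of 2440.5 and 1503 UMIs. T cell-like cells of the control libraries and of the later libraries had 0 counts, and B cell-like cells of the later libraries had 5, 2, 4 and 6 counts (durable, progressive, day 28, vaccine). GFP was found in 13 T cell-like cells of the FR-B and anti-PD-1 library, 7 of which also carried BiTE, and in 2 or fewer T cell-like cells of each other library. Luciferase had at most 2 counts in the T cell-like cells of any library.

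The epithelial-like cells of the later libraries carried almost none of the added sequences. hFRa had 0 counts in 232 cells of the durable library (floor 0.283 CPM), 0 in 1421 cells at day 28 (floor 0.063 CPM) and 0 in 606 cells with vaccine (floor 0.135 CPM). In the progressive library 21 of 1829 cells held 322 counts, 9.96 CPM (8.90 to 11.1), or 0.711% of cells after thinning with 1 left out, where B cell-like cells were at 0.356% before and 0.732% after thinning with 433 left out, at medians of 16625 and 985 UMIs. Per cell the 2 classes differed, with up to 72 hFRa counts in an epithelial-like cell and at most 1 in a B cell-like cell. A few epithelial-like cells of that library thus held many hFRa counts. GFP was at 0, 3.25, 0.042 and 0 CPM in the durable, progressive, day 28 and vaccine libraries. Against day 7 this difference also goes with sorting and time, which cannot be told apart from treatment.

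Cluster 7, unnamed and led by Hmox1, Cbr2, F13a1, Trem2, Lyve1 and Folr2, held 24.1% of the progressive library and 5.74% at day 28, against 0.624% (durable) and 0.193% (vaccine). Cluster 13, unnamed and led by Cxcl9, Cx3cr1 and Ccr2, held 5.57% with control T cells and anti-PD-1 and between 1.20% and 2.20% in each other library. Cluster 11, unnamed and led by Retnla, Lyz1 and Ear2, held 6.34% with FR-B T cells and isotype and 8.53% with FR-B T cells and anti-PD-1, against 1.61% and 1.09% with control T cells. Cluster 18, unnamed with epithelial markers and few UMIs, held 4.83% at day 28 and 1.56% with vaccine. Mast cell-like cells were 1.63% (progressive), 2.64% (day 28) and 1.60% (vaccine), and 0.862% or less elsewhere. Within macrophage clusters 2 and 6 the FR-B effect on interferon-gamma-induced genes was 1.09 and 0.41 with isotype and -0.53 and -0.07 with anti-PD-1, and the anti-PD-1 effect with FR-B T cells was 0.73 and 1.05.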
